A study of Mus musculus with 15 samples.

How the data were processed

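RNA was measured by sequencing in 15 plantaris muscles, 1 library each, from adult male HSA-GFP mice. These mice carry an inducible, muscle-specific transgene that labels the nuclei of muscle fibres with a fluorescent histone. Mice entered the study at 4 months of age. Trained mice did progressive weighted wheel running (PoWeR), in which a load on the running wheel is raised over time, for 8 weeks and were sampled at 6 months. Detrained mice did the same training and then 12 weeks of detraining, and were sampled at 9 months. Untrained mice of 6 and 9 months were the controls. Muscles were frozen in liquid nitrogen and RNA was taken out with TRIzol and a Zymo kit, per the labels' protocols.

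Libraries were grouped by their titles into 6M_UT (untrained, 6 months), 6M_PoW (trained, 6 months), 9M_UT (untrained, 9 months), 9M_PoW+DT (detrained, 9 months) and 6M_POW_LD, which held the libraries titled as trained replicates 4 to 6 with LD identifiers. What LD stands for is not given in the sources used here. Each of the 5 groups held 3 libraries. The treatment field contradicted the title in 9 libraries. It named the other condition for all 6 of the 9-month libraries and called the 3 LD libraries sedentary. The direction of every comparison that uses the 9-month groups or the LD libraries therefore rests on the titles. Both other readings were run as alternatives for gene calls and single genes, but not for the tests of the gene lists described below. The library identifiers also differed between the 6-month, 9-month and LD libraries, so age and library series could not be separated. Identifiers differed for every library, but nothing in the labels said that replicates were separate mice, and p-values measure only the spread between these samples.

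The authors deposited 1 table of expected counts per gene, listing 20406 genes in all 15 libraries. Between 25.8% and 30.8% of a library's values were not whole numbers, and the smallest sum over the 15 libraries was 10. In the deposited table, the 18 values of 1000000 or more were written with 3 significant digits, and they belonged to Myh4 and mt-Co1. STAR 2.7.3a, DESeq2 and Partek and the mouse build mm10 were named per the submitters' processing notes, without their roles. The counting method, its use of strand and the annotation release are not given in the sources used here. Values of overlapping or antisense genes, of gene families with near-identical members and of mitochondrial genes with nuclear copies are therefore uncertain. Gene starts are given as in the deposited table and gene ends as its stop position less 1, counted from 1, on mm10.

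Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, which left 14919 genes for the 12 libraries of the 4 groups without LD and 15181 genes for all 15 libraries. Counts were scaled by the trimmed mean of M values, and a quasi-likelihood model with robust dispersion was fitted with 1 mean per group (edgeR 4.0.16, R 4.3.3). The 5 comparisons without LD libraries were taken from the fit of 12 libraries, and the 2 with LD libraries from the fit of 15. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and genes with an adjusted p under 0.05 were called. Each log2 fold change is given with its standard error (SE). Levels are in CPM, counts scaled to an effective library total of 1000000, as mean ± SD over the 3 libraries of a group.

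There were 34 gene lists for muscle fibre types, energy metabolism, translation, cell types, stress and stimulus responses, the clock, cell cycle, DNA methylation, Hox genes and candidate memory genes. The 32 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 (limma 3.58.1), adjusted over the 32 lists of a comparison. T and B cell markers and neutrophil markers, with 2 and 3 tested members, were not tested. Each list was also tested with camera and an estimated correlation, and with fry, whose directional p asks whether a list moves one way and does not compare it with other genes. Calls within a list are also given adjusted over the list alone. Of the 68 list results that passed with the preset correlation, 2 passed with the estimated correlation. Both were for immediate early genes, in detrained against untrained mice and in older against younger untrained mice.

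The named genes followed a rule. They were the 8 largest rises and 8 largest falls of a comparison (4 and 4 for LD comparisons) among called genes with an average log2 CPM of at least 2, no overlap between the groups (not asked of the difference of contrasts) and an official symbol. In the training and detraining comparisons and their difference, Myh7, Myh2, Myh1, Myh4, Ppargc1a, Mstn, Igf1 and Vegfa were added. Up to 4 members with the smallest p of each list that passed were added too. So were up to 10 genes called in the same direction in both the training and the detraining comparison. Where fewer than 5 genes were called, these and the 5 genes with the smallest p were named. Fewer genes are named than the rule gives. The groups, tests, lists, rule and alternatives were fixed before the data were examined, except where the text says otherwise.

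Library totals ran from 18865048 to 27688842 counts, and genes of the mitochondrial genome took 16.0% to 22.5% of them. No pair of libraries of one group agreed within counting noise. The lowest variance ratio of such a pair was 4.42, where counting noise alone gives 1, so no library was counted as a repeat of another. The procedure was tested on simulated counts with the libraries of the 4 groups without LD as model. In the training comparison 200 of 14666 genes were changed, and a gene list was also raised by 0.5 on the log2 scale. That list had a fitted median of 0.54. The procedure recovered 19.7% of genes changed 1.5-fold, 57.6% of those changed 2-fold and 80.3% of those changed 4-fold. It called 9 unchanged genes, a count that leaves out the raised list. A 1.5-fold change was thus mostly below what 3 libraries against 3 showed. DESeq2 recovered 27.3% and 65.2% of the 1.5-fold and 2-fold changes there and called 23 unchanged genes.

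The alternatives were relative log expression size factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, the replicate number as a block, counts thinned to the smallest library, each library left out in turn, the 9-month groups exchanged, and the LD libraries added to the trained or to the untrained group. A fit with 1 surrogate variable (sva 3.50.0) was chosen after the data had been seen. No reads and no methylation data were used here.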

Results

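Plantaris RNA was compared between untrained, trained and detrained mice in 15 libraries of 5 groups, with 3 libraries in each. The totals were 22678556 to 27688842 counts in 6M_UT, 20779761 to 26135003 in 6M_PoW and 23743635 to 26869821 in 6M_POW_LD. They were 18865048 to 21693866 in 9M_UT and 20614662 to 22451440 in 9M_PoW+DT. The fast myosin gene Myh4 and mitochondrial transcripts took large shares of the counts, and the 10 most abundant genes of a library held 24.9% to 27.9% of its total. Between 17725 and 18616 of the listed genes had a count in a library.

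Training for 8 weeks was compared with no training at 6 months to ask which transcripts PoWeR moved in the plantaris. Genes of the extracellular matrix rose together after training, with a median log2 fold change of 0.53 over 33 collagen and matrix genes, of which 31 lay above 0. Markers of fibro-adipogenic progenitors, the connective tissue cells of muscle, rose by a median of 0.35 over 14 genes, and markers of macrophages and other leukocytes rose by 0.46 over 16 genes. Endothelial markers rose by a median of 0.29 over 14 genes and interferon-stimulated genes by 0.45 over 18. Fast fibre genes, glycolysis and glycogen genes, ribosomal proteins and ribosome biogenesis genes fell by 0.16, 0.13, 0.11 and 0.15 on the log2 scale. These lists passed camera with the preset correlation, at an adjusted p of 9.2e-19 for the matrix genes, 2.0e-09 for the progenitor markers, and 2.0e-06 for the leukocyte markers. It was 1.3e-04 for both the endothelial and the interferon lists, 0.0145 for fast fibre genes, 0.00218 for glycolysis and for ribosomal proteins, and 0.00226 for ribosome biogenesis. None passed otherwise, with adjusted p = 0.134 with an estimated correlation for the matrix genes, adjusted p = 0.142 for the progenitor markers and adjusted p = 0.183 to 0.661 for the other lists. The fast fibre result ended without 6M_UT replicate 1, 6M_PoW replicate 1 or 6M_PoW replicate 2, with medians of -0.12, -0.10 and -0.14 (adjusted p = 0.0841, 0.193 and 0.0588). Those of glycolysis and ribosome biogenesis ended without 6M_UT replicate 1, with medians of -0.07 and -0.08 (adjusted p = 0.0690 for each). That of ribosomal proteins ended without 6M_PoW replicate 1 (median -0.08, adjusted p = 0.0632) and stood at -0.05 without 6M_PoW replicate 2.

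Single genes did not pass in edgeR, which called 0 of 14919 genes, with 1455 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0701. That adjusted p was shared by 5 genes. Fam57b (chromosome 7, 126797668 to 126830219) stood at 33.4 ± 5.62 CPM in trained and 59.1 ± 6.53 CPM in untrained muscle, a log2 fold change of -0.82 ± 0.12 (SE). The RNA-binding protein gene Msi2 (chromosome 11, 88339382 to 88718513) stood at 164 ± 4.80 and 212 ± 8.34 CPM. Trp53i11 (chromosome 2, 93187548 to 93201759) stood at 13.3 ± 1.38 and 5.54 ± 0.261 CPM, a log2 fold change of 1.26 ± 0.21. The collagen chain gene Col5a2 (chromosome 1, 45374321 to 45503282) stood at 14.98 ± 2.09 and 7.50 ± 1.06 CPM, and the matrix protease gene Mmp2 (chromosome 8, 92827291 to 92853420) at 31.6 ± 3.09 and 18.9 ± 1.24 CPM. Adjusted over the list alone, 17 of the 33 matrix genes, 8 of the 14 progenitor markers, 4 of the 14 endothelial markers and 2 of the 16 leukocyte markers passed, all of them higher, beside 0 over all genes tested. Among these, the log2 fold change was 0.54 ± 0.10 for the basement membrane collagen Col4a1, 0.56 ± 0.14 for Cd34, 0.88 ± 0.23 for lumican (Lum), 0.39 ± 0.12 for Pdgfra, and 0.44 ± 0.12 for the endothelial cadherin Cdh5. It was 0.46 ± 0.14 for the receptor Tek, 0.67 ± 0.13 for lysozyme (Lyz2) and 0.70 ± 0.18 for the mannose receptor Mrc1. In the lists with no member past that test, it was 1.34 ± 0.41 for Ifit3, -0.19 ± 0.09 for the calcium pump gene Atp2a1, -0.17 ± 0.06 for Tpi1 of glycolysis, -0.22 ± 0.07 for Rpl4 and -0.29 ± 0.11 for Bop1. The growth factor gene Igf1 stood at 10.8 ± 2.06 CPM in trained and 4.65 ± 0.861 CPM in untrained muscle (log2 fold change 1.21 ± 0.22, edgeR adjusted p = 0.118). DESeq2 called 112 genes, 58 higher and 54 lower, and limma-voom 0. In edgeR 10 genes were called without 6M_UT replicate 3, 9 without 9M_PoW+DT replicate 3, 2 without 9M_PoW+DT replicate 1 and 1 without 6M_PoW replicate 2.

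**Figure D1:**
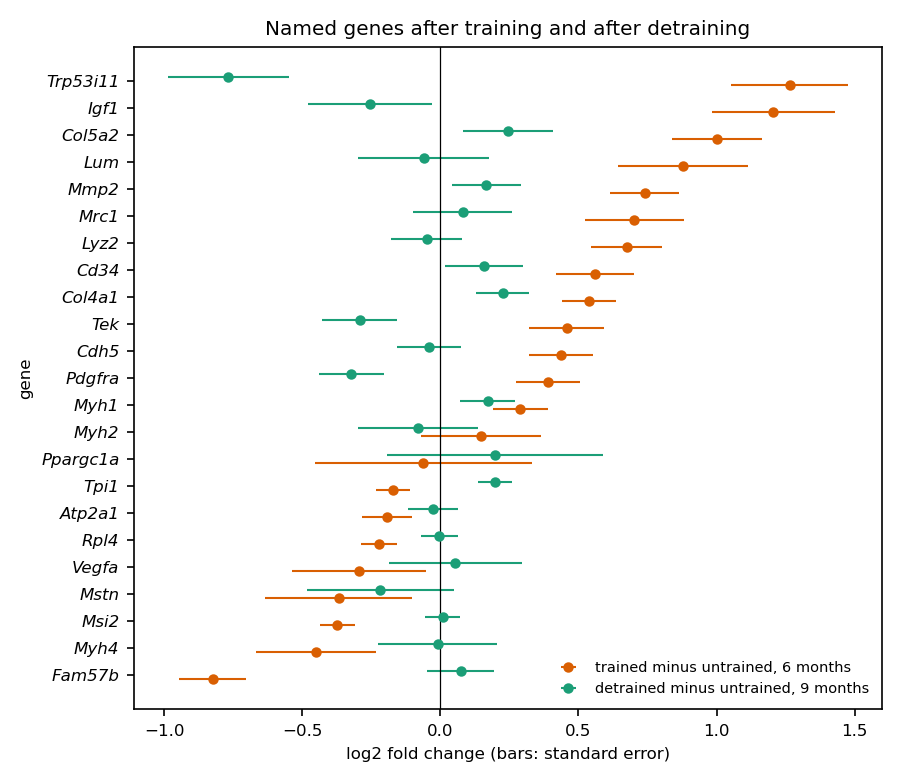
Log2 fold changes of 23 named genes in the training comparison (6M_PoW minus 6M_UT, orange) and the detraining comparison (9M_PoW+DT minus 9M_UT, green), with bars for the standard error of the edgeR fit and 3 libraries per group. Trp53i11 lies at 1.26 after training and at -0.77 after detraining, and Igf1 at 1.21 and -0.25.

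Detrained mice were compared with untrained mice of 9 months to ask which transcripts differed between them 12 weeks after training had ended. Tmem232, a transmembrane protein gene, was lower in the detrained mice, at 0.105 ± 0.0644 CPM against 5.13 ± 0.979 CPM in the untrained mice. Fosl2, a member of the AP-1 transcription factors, was lower at 12.4 ± 1.64 against 32.6 ± 7.47 CPM, and the nuclear receptor gene Nr4a2 at 0.942 ± 0.545 against 6.19 ± 0.773 CPM. Immediate early genes, which cells switch on within minutes of a stimulus, were lower as a list. The median was 0.64 lower on the log2 scale, with 19 of 20 members below 0. Here too 9M_UT stood apart, with list means of 3.73 to 3.95 on the log2 CPM scale. In 6M_UT, 6M_PoW and 9M_PoW+DT these means were at most 3.39. Genes of the mitochondrial genome for oxidative phosphorylation fell by 0.23, with 13 of 13 below 0, while the 52 nuclear genes for the same machinery rose by 0.06. Both of these lists were lost otherwise, with adjusted p = 0.488 and 0.792 with an estimated correlation, and the nuclear list stood at 0.016 without 9M_PoW+DT replicate 1 (adjusted p = 0.530). Without 9M_UT replicate 1 or 9M_PoW+DT replicate 1 the immediate early list stood at -0.40, and without 9M_UT replicate 3 the mitochondrial genome list stood at -0.15.

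These 3 genes were the calls in edgeR, and 0 genes were called higher, with 972 of 14919 genes at an unadjusted p under 0.05. The log2 fold change was -5.52 ± 0.63 for Tmem232 (chromosome 17, 65255999 to 65540782, edgeR adjusted p = 0.00296), -1.40 ± 0.19 for Fosl2 (chromosome 5, 32135801 to 32157842, adjusted p = 0.0209) and -2.70 ± 0.39 for Nr4a2 (chromosome 2, 57106830 to 57124003, adjusted p = 0.0209). DESeq2 called 30 genes and limma-voom 0, with an adjusted p of 0.0795 for each of the 3. With a stricter filter on low counts edgeR called 0, as Tmem232 was no longer tested and Fosl2 and Nr4a2 had an adjusted p of 0.0509. The call of Tmem232 held without each library in turn. That of Fosl2 ended without 6M_PoW replicate 2, 9M_UT replicates 2 or 3 or any 9M_PoW+DT replicate (adjusted p = 0.0535 to 0.121). It also ended with the replicate number as a block (log2 fold change -1.39, adjusted p = 0.116). That of Nr4a2 ended without 6M_PoW replicate 2, any 9M_UT replicate or 9M_PoW+DT replicates 2 or 3 (adjusted p = 0.0535 to 0.163). There were 6 calls without 6M_UT replicate 1, 5 without 6M_UT replicates 2 or 3, 2 without 9M_UT replicates 1 or 2 or 9M_PoW+DT replicate 2, and 1 without 6M_PoW replicate 2, 9M_UT replicate 3 or 9M_PoW+DT replicate 3.

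**Figure D2:**
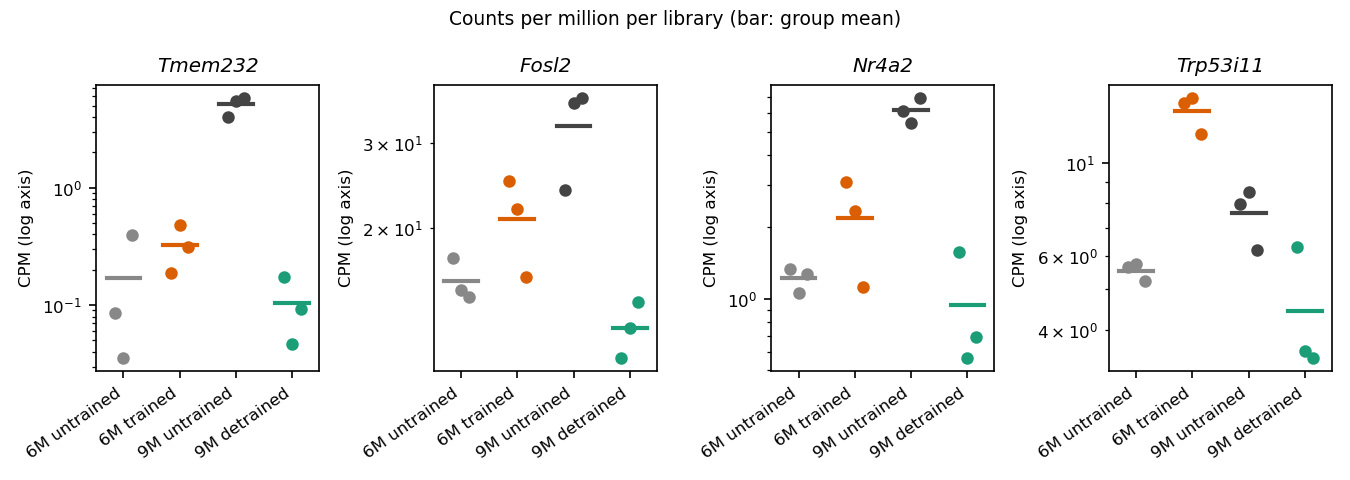
Levels in CPM on a log axis of the 4 genes called in the detraining comparison or in its difference from the training comparison, with 1 point per library and a bar for the group mean. Tmem232 lies between 4.01 and 5.86 CPM in 9M_UT and at or below 0.481 CPM in the other libraries shown.

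Among the gene groups of the detraining comparison, immediate early genes passed the set test at an adjusted p of 3.6e-17, with adjusted p = 0.0316 with an estimated correlation and adjusted p = 0.0282 by fry. Of the 20 members, 2 were called over all genes and 7 were lower when adjusted over the list alone. Atf3 stood at 7.21 ± 1.96 CPM in detrained and 24.7 ± 10.5 CPM in untrained muscle, and Klf4 at 18.7 ± 7.001 and 48.1 ± 4.41 CPM. The mitochondrial genome list passed at an adjusted p of 6.4e-07 (adjusted p = 0.488 with an estimated correlation), with 0 members called over all genes and 8 lower adjusted over the list alone. The log2 fold change was -0.27 ± 0.08 for mt-Co1 and -0.32 ± 0.08 for mt-Co2, whose reads can be shared with nuclear copies of mitochondrial genes. Embryonic and regeneration genes fell by a median of 0.49 (adjusted p = 7.6e-04, adjusted p = 0.350 with an estimated correlation), and the stretch-responsive gene Ankrd1 stood at 10.5 ± 1.89 against 19.4 ± 2.53 CPM. Endothelial markers fell by 0.20 (adjusted p = 8.9e-04, adjusted p = 0.350 with an estimated correlation), with Flt1 at -0.35 ± 0.12. Atrophy genes fell by 0.27 (adjusted p = 0.00225, adjusted p = 0.712 with an estimated correlation), with the mitophagy gene Bnip3 at -0.31 ± 0.12. Matrix genes rose by 0.17 (adjusted p = 0.00699, adjusted p = 0.596 with an estimated correlation), with Sparc at 0.37 ± 0.09, and Schwann cell markers rose by 0.33 (adjusted p = 0.00514, adjusted p = 0.488 with an estimated correlation). The nuclear oxidative phosphorylation list passed at an adjusted p of 0.0301 (adjusted p = 0.792 with an estimated correlation). Adipocyte markers rose by 0.81 (adjusted p = 0.00190, adjusted p = 0.596 with an estimated correlation), but 9M_PoW+DT replicate 3 alone held 16.9 CPM of Lep and 14.5 CPM of Adipoq, where the other 14 libraries held at most 3.69 and 4.79 CPM. Without that library the adipocyte list had a median of 0.18 and an adjusted p of 0.494, and the endothelial list a median of -0.12 and an adjusted p of 0.132, while the matrix list stood at 0.27 and the nuclear oxidative phosphorylation list at 0.11. The nuclear oxidative phosphorylation result ended without 9M_UT replicates 1 or 3 or 9M_PoW+DT replicates 1 or 2, with medians of 0.041, 0.039, 0.016 and 0.023 (adjusted p = 0.130, 0.229, 0.530 and 0.223). That of the matrix genes ended without 9M_UT replicate 2 or 9M_PoW+DT replicate 1, with medians of 0.14 and 0.11 (adjusted p = 0.0964 and 0.207). That of Schwann cell markers ended without 9M_UT replicate 2 or 9M_PoW+DT replicates 1 or 2, with medians of 0.14, 0.21 and 0.22 (adjusted p = 0.215, 0.0543 and 0.0599). That of atrophy genes ended without 9M_UT replicate 3 or 9M_PoW+DT replicate 1, with medians of -0.16 and -0.19 (adjusted p = 0.258 and 0.341), and its median was -0.41 without 9M_UT replicate 1. The median of immediate early genes was -0.40 without 9M_UT replicate 1 or 9M_PoW+DT replicate 1, and that of the mitochondrial genome was -0.15 without 9M_UT replicate 3.

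The difference between the detraining and the training comparison was then tested. It asks which transcripts differed from their age-matched controls by another amount after detraining than after training. Both effects can have the same direction, as for collagen and matrix genes, which were higher as a list in both comparisons. Trp53i11 was 2.40-fold the untrained level after training and lay below it after detraining, at 4.44 ± 1.62 against 7.58 ± 1.22 CPM. Against their age-matched controls, Tmem232, Fosl2 and Nr4a2 were lower after detraining and not after training. The group that stood apart for Tmem232 was 9M_UT, at 4.01 to 5.86 CPM. Libraries of 6M_UT, 6M_PoW and 9M_PoW+DT held at most 0.481 CPM. As lists, collagen and matrix genes, endothelial, progenitor and leukocyte markers, immediate early genes and genes of the mitochondrial genome moved down in the difference, and fast fibre genes, glycolysis genes, ribosomal proteins and adipocyte markers moved up. These moves passed only with the preset correlation, with adjusted p = 0.0993 to 0.558 with an estimated correlation. Igf1 had a difference of -1.46 ± 0.32 on the log2 scale and did not pass (edgeR adjusted p = 0.181).

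In that test edgeR called 4 of 14919 genes, all lower, with 1414 at an unadjusted p under 0.05. The log2 difference, detraining minus training, was -6.52 ± 0.92 for Tmem232, -1.82 ± 0.27 for Fosl2, -3.54 ± 0.55 for Nr4a2 and -2.03 ± 0.30 for Trp53i11, each with an edgeR adjusted p of 0.0330. The translation factor gene Eef1a1 followed at -0.55 ± 0.09 (adjusted p = 0.0581). Over the lists alone, 6 endothelial markers, 2 progenitor markers and 1 leukocyte marker were lower, and the difference was -0.75 ± 0.19 for Tek, -0.71 ± 0.17 for Pdgfra and -0.72 ± 0.18 for Lyz2, beside 0 of them over all genes tested. It was -0.45 ± 0.11 for mt-Co1, 0.37 ± 0.09 for Tpi1 and 5.80 ± 1.11 for Lep, which did not pass over all genes (edgeR adjusted p = 0.181) and stood at 4.57 without 9M_PoW+DT replicate 3. The list results had adjusted p of 3.7e-07 for endothelial and 4.3e-06 for progenitor markers, 4.9e-05 for the matrix, and 1.5e-09 for immediate early genes. It was 5.0e-04 for the mitochondrial genome, 0.00195 for leukocyte markers, 0.0157 for fast fibre genes, 0.00494 for ribosomal proteins and 0.00241 for glycolysis and for adipocyte markers. None passed otherwise, with adjusted p = 0.0993 with an estimated correlation for endothelial markers and immediate early genes and adjusted p = 0.278 to 0.558 for the others. DESeq2 called 111 genes and limma-voom 0. With one library left out, edgeR called 26 genes without 6M_UT replicate 3 and 7 without 9M_PoW+DT replicate 1, 1 without 9M_UT replicate 1 or 9M_PoW+DT replicate 2, and 0 without 6M_UT replicate 2, 6M_PoW replicates 1 or 2, 9M_UT replicates 2 or 3 or 9M_PoW+DT replicate 3. The fast fibre result ended without 6M_UT replicate 1, 6M_PoW replicate 1, 9M_UT replicate 1 or 9M_PoW+DT replicate 3 (adjusted p = 0.0605, 0.122, 0.0832 and 0.153). That of ribosomal proteins ended without 6M_PoW replicate 1 or 9M_UT replicate 1 (adjusted p = 0.0546 and 0.0718). That of adipocyte markers, with a median of 1.197, stood at 0.53 without 9M_PoW+DT replicate 3 (adjusted p = 0.0586) and at 0.70 without 6M_UT replicate 1. Immediate early genes, with a median of -0.36, stood at -0.66, -0.69 and -0.59 without 6M_UT replicate 1, 9M_PoW+DT replicate 2 and 9M_PoW+DT replicate 3. The matrix median of -0.33 was -0.51 without 6M_UT replicate 2, and the progenitor median of -0.40 was -0.26 without 6M_PoW replicate 2. The leukocyte median of -0.42 was -0.28 without 9M_PoW+DT replicate 3, and the mitochondrial genome median of -0.25 was -0.15 without 9M_UT replicate 3. With the replicate number as a block Fosl2 lost its call (log2 difference -1.82, adjusted p = 0.0928). DESeq2 gave Tmem232 no adjusted p (log2 difference -6.62) and called the other 3 of the 4 genes. The calls ended in limma-voom (adjusted p = 0.119 for each). With LD libraries added to the trained group they ended for Tmem232 (-5.83, adjusted p = 0.109) and Trp53i11 (-1.73, adjusted p = 0.166). With these added to the untrained group they ended for Fosl2 (-1.555, adjusted p = 0.179), Nr4a2 (-2.72, adjusted p = 0.286) and Trp53i11 (-1.71, adjusted p = 0.231). With the 9-month groups exchanged Trp53i11 stood at -0.50 and Tmem232, Fosl2 and Nr4a2 at 4.53, 0.97 and 1.86, and none passed (adjusted p = 0.747, 0.362, 0.612 and 0.612).

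Genes chosen at an unadjusted p under 0.01 after training did not, as sets, hold their direction after detraining. The 199 genes higher after training at an unadjusted p under 0.01 had a median log2 fold change of 0.61 after training and -0.04 after detraining, and 41.2% of them had the same sign in both. The 221 genes lower at that threshold had medians of -0.33 and 0.03, with the same sign in 40.3%. In the detraining comparison the higher set lay below the other genes at an unadjusted camera p of 0.00426, but p = 0.343 with an estimated correlation and 0.301 by fry, and the lower set had a camera p of 0.224. These sets were chosen after the data had been seen, since edgeR called 0 genes in the training comparison and the planned sets were empty. Part of their genes can differ by chance, and the direction of such genes need not hold. Among lists that passed in both comparisons with the preset correlation, collagen and matrix genes were higher in both. Endothelial markers were higher after training and lower after detraining. Chosen again without 6M_UT replicate 2, the sets held 226 higher and 233 lower genes, of which 132 and 146 were in the first sets, and their medians after detraining were 0.01 and -0.01. The higher set had a median of 0.01 without 9M_UT replicate 1 (209 genes) and 0.00 without 9M_PoW+DT replicate 3 (218 genes). Across 11339 genes with an average log2 CPM of at least 1, the fold changes of both comparisons had a Pearson correlation of -0.08, and genes are not independent replicates. No gene was called in both comparisons by edgeR, and DESeq2 called 1 gene in both in the same direction. Genes that DESeq2 called in both in opposite directions were not counted.

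Detrained mice of 9 months were also set against trained mice of 6 months, a comparison in which detraining, age and library series change together. Nuclear genes of oxidative phosphorylation fell by a median of 0.14 on the log2 scale over 52 genes, those of the mitochondrial genome by 0.18 over 13 and those of fatty acid uptake and oxidation by 0.19 over 25. Cox7a1, the muscle form of a cytochrome c oxidase subunit, fell to 81.5 ± 15.5 CPM in detrained from 145 ± 8.90 CPM in trained muscle. It was as low in untrained mice of 9 months, at 77.1 ± 3.98 CPM, against 112 ± 8.37 CPM in those of 6 months. Its low level was thus not particular to detrained mice. Ndufc1 of complex I fell to 57.5 ± 2.38 from 79.8 ± 3.34 CPM and the electron transfer flavoprotein gene Etfa to 135 ± 10.02 from 178 ± 4.24 CPM. Endothelial and progenitor markers fell by 0.36 and 0.27, and interferon-stimulated genes by 0.62. Fast fibre genes rose by 0.20, glycolysis genes by 0.11 and tendon markers by 0.44, and adipocyte markers by 0.93. All of these list results were lost otherwise, with adjusted p = 0.303 to 0.606 with an estimated correlation.

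In this comparison 44 of 14919 genes were called, 22 higher and 22 lower, with 1897 at an unadjusted p under 0.05. Trp53i11 had a log2 fold change of -1.58 ± 0.22, Cox7a1 of -0.84 ± 0.11 and Tceal7 of 0.99 ± 0.14, each with an edgeR adjusted p of 0.0104. The ubiquitin ligase gene Mib1 rose to 355 ± 58.0 CPM in detrained from 145 ± 24.1 CPM in trained muscle (log2 fold change 1.30 ± 0.17), and Cdc42bpg and Adgrl1 rose by 1.03 ± 0.16 and 0.64 ± 0.11. Gclm of glutathione synthesis and the collagen receptor gene Itga1 fell by 0.81 ± 0.14 and 0.86 ± 0.15. Lep had a log2 fold change of 5.48 ± 0.86 (adjusted p = 0.0317), with 16.9 CPM in 9M_PoW+DT replicate 3, 3.69 and 3.05 CPM in the other detrained and 0.111 to 0.225 CPM in the trained libraries. Without that replicate, Lep stood at 4.26 and kept its call. Adjusted over the lists alone, 10 nuclear and 3 mitochondrial oxidative phosphorylation genes, 5 genes of fatty acid oxidation and 5 endothelial markers were lower, beside 2, 0, 1 and 0 over all genes tested, with log2 fold changes of -0.37 ± 0.08 for Cox6c, -0.43 ± 0.10 for Acadl and -0.48 ± 0.12 for Cdh5. Over the fast fibre list alone 2 genes were higher and 1 was lower, and the log2 fold change was 0.29 ± 0.07 for the calcium buffer gene Pvalb, 0.62 ± 0.22 for Myh4 and -0.32 ± 0.10 for Myh1. Ifit3 of the interferon list stood at 1.22 ± 0.607 against 2.71 ± 0.864 CPM. The list results had adjusted p of 9.9e-07 for nuclear and 3.8e-04 for mitochondrial oxidative phosphorylation, 3.0e-06 for fatty acid oxidation and for adipocyte markers, and 3.4e-06 for endothelial markers. It was 2.4e-05 for interferon-stimulated genes, 2.8e-04 for fast fibre genes, 0.0105 for progenitor markers, 0.0188 for glycolysis and 0.0231 for tendon markers. None passed otherwise, with adjusted p = 0.303 with an estimated correlation for endothelial markers and adjusted p = 0.587 to 0.606 for the other lists. Without 9M_PoW+DT replicate 3 the adipocyte median of 0.93 was 0.31 and the mitochondrial one of -0.18 was -0.11, and without 6M_PoW replicate 2 the interferon median of -0.62 was -0.31.

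Between detrained and trained mice, all 44 calls ended without 6M_PoW replicate 2, although the log2 fold changes of Trp53i11, Cox7a1, Tceal7 and Mib1 stayed at -1.53, -0.87, 0.95 and 1.18 (adjusted p = 0.0665 for each). The count was 11 without 9M_PoW+DT replicate 3, 12 without 6M_PoW replicate 1, 27 without 6M_PoW replicate 3, 29 without 9M_UT replicate 2 and 109 without 6M_UT replicate 1. The call of Mib1 also ended without 6M_PoW replicate 3 or 9M_PoW+DT replicate 3 (adjusted p = 0.0600 and 0.0751). That of Cdc42bpg ended without 6M_PoW replicate 2 or 9M_PoW+DT replicate 3 (adjusted p = 0.0736 and 0.0751). Ndufc1 lost its call without 6M_PoW replicates 1 or 2 or 9M_PoW+DT replicates 2 or 3 (adjusted p = 0.0546 to 0.0869), Gclm without 6M_PoW replicates 2 or 3 or 9M_PoW+DT replicates 2 or 3 (adjusted p = 0.0510 to 0.0948), Itga1 without 6M_PoW replicates 1 or 2 or 9M_PoW+DT replicates 2 or 3 (adjusted p = 0.0829 to 0.146) and Adgrl1 without any 6M_PoW replicate or 9M_PoW+DT replicate 3 (adjusted p = 0.0525 to 0.146). Etfa lost it without any 6M_PoW, 9M_UT or 9M_PoW+DT replicate (adjusted p = 0.0541 to 0.161), and Lep without 6M_UT replicate 2, any 6M_PoW replicate or 9M_UT replicates 1 or 2 (adjusted p = 0.0530 to 0.174). With the 9-month groups exchanged 50 genes were called, 16 of them among the 44. The calls then ended for Trp53i11 (log2 fold change -0.81, adjusted p = 0.127), Gclm (-0.39, adjusted p = 0.266), Itga1 (-0.49, adjusted p = 0.207), Adgrl1 (0.43, adjusted p = 0.136), Etfa (-0.35, adjusted p = 0.0657) and Lep (3.02, adjusted p = 0.231). With the replicate number as a block they ended for Adgrl1, Gclm, Etfa and Lep (adjusted p = 0.0553, 0.0528, 0.0704 and 0.0768). With the LD libraries added to the trained group, Tceal7 had a log2 fold change of 0.11 and an adjusted p of 0.927, and Gclm one of -0.54 and an adjusted p of 0.168. DESeq2 called 348 genes and limma-voom 24. Etfa and Lep lost their calls in limma-voom (adjusted p = 0.0519 and 0.193) and in a fit of only the 2 groups (adjusted p = 0.0565 and 0.138). The glycolysis result ended without 6M_PoW replicates 1 or 2 or 9M_PoW+DT replicates 1 or 3, with medians of 0.10, 0.07, 0.11 and 0.06 (adjusted p = 0.0714, 0.0947, 0.0506 and 0.102). That of progenitor markers ended without 6M_PoW replicate 2 or 9M_PoW+DT replicate 1, with medians of -0.17 and -0.20 (adjusted p = 0.258 and 0.0794). That of tendon markers ended without 6M_PoW replicate 3 or 9M_PoW+DT replicate 1, with medians of 0.36 and 0.29 (adjusted p = 0.0771 and 0.448).

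Untrained mice of 9 months were compared with untrained mice of 6 months, a comparison in which age and library series change together and cannot be told apart. Atf3, a stress-induced transcription factor gene, was higher in the older mice, at 24.7 ± 10.5 against 5.70 ± 0.992 CPM, and Tmem232 at 5.13 ± 0.979 against 0.172 ± 0.194 CPM. Immediate early genes rose as a list by a median of 0.65 on the log2 scale, with 18 of 20 above 0. Nuclear oxidative phosphorylation genes fell by 0.12, with 51 of 52 below 0, fatty acid oxidation genes by 0.15, with 25 of 25 below 0, and ribosomal proteins by 0.12. Leukocyte, progenitor, matrix, tendon and satellite cell genes rose by 0.38, 0.26, 0.24, 0.56 and 0.22. Except for immediate early genes, these lists had adjusted p = 0.327 to 0.473 with an estimated correlation.

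Here edgeR called 2 of 14919 genes, both higher, with 1003 at an unadjusted p under 0.05. DESeq2 called 58 and limma-voom 0. The log2 fold change was 4.91 ± 0.58 for Tmem232 (edgeR adjusted p = 0.00541) and 2.12 ± 0.28 for Atf3 (adjusted p = 0.0302). The next were Nr4a2 at 2.34 ± 0.38, Ankrd1 at 1.18 ± 0.20, the phosphatase gene Dusp7 at -1.33 ± 0.21 and Rps6 at -0.83 ± 0.14, each with an adjusted p of 0.0554, and Fosl2 stood at 1.07 ± 0.19 (adjusted p = 0.0876). Adjusted over the lists alone, 7 immediate early genes and 3 progenitor markers were higher, and 8 nuclear oxidative phosphorylation genes and 4 ribosomal proteins were lower, beside 1, 0, 0 and 0 over all genes tested. On the log2 scale, the fold change was -0.54 ± 0.11 for Cox7a1, -0.59 ± 0.11 for Cox8b, -0.46 ± 0.09 for Rpl14, 0.45 ± 0.12 for Pdgfra, 0.36 ± 0.08 for Serping1 and 0.37 ± 0.13 for Lyz2. The immediate early list passed at an adjusted p of 2.7e-16, with adjusted p = 0.0361 with an estimated correlation and adjusted p = 0.0352 by fry. The other lists passed only with the preset correlation, at an adjusted p of 1.7e-11 for nuclear oxidative phosphorylation, 3.8e-06 for ribosomal proteins, 2.9e-05 for leukocyte, 8.4e-05 for matrix and 1.3e-04 for progenitor genes. It was 1.6e-04 for fatty acid oxidation and for embryonic and regeneration genes (median 0.33), 0.00150 for tendon, 0.0296 for endothelial (median 0.08), 0.0305 for interferon-stimulated (median -0.33), 0.0383 for satellite cell and 0.0424 for Schwann cell genes (median -0.14). They had adjusted p = 0.301 to 0.473 with an estimated correlation. The call of Atf3 ended without any 6M_UT replicate or 6M_PoW replicates 1 or 2 (adjusted p = 0.0505 to 0.253). It also ended with a stricter filter (adjusted p = 0.0630), where Tmem232 was not tested, in a fit of only the 2 groups (adjusted p = 0.105) and with LD libraries added to the untrained group (1.60, adjusted p = 0.1502). In limma-voom neither gene passed (adjusted p = 0.0563 for both). With the 9-month groups exchanged, so that detrained mice stood for the older untrained ones, Atf3 stood at 0.34 (adjusted p = 0.967) and Tmem232 at -0.61 (adjusted p = 0.982). The count of calls was 15 without 9M_PoW+DT replicate 3, 6 without 9M_PoW+DT replicate 2, 5 without 6M_UT replicate 3, 6M_PoW replicate 3 or 9M_PoW+DT replicate 1, and 1 without 6M_UT replicate 2 or 6M_PoW replicate 2. Every 6M_UT or 9M_UT replicate left out ended at least 1 of the list results (adjusted p = 0.0501 to 0.685). Matrix and tendon genes did not pass without 6M_UT replicate 1 (medians 0.13 and 0.33). Endothelial, satellite cell, Schwann cell and interferon genes did not without 6M_UT replicate 2 (medians 0.01, 0.11, -0.11 and -0.19). Fatty acid, satellite cell, Schwann cell and interferon genes did not without 6M_UT replicate 3 (medians -0.06, 0.25, -0.19 and -0.11). Endothelial, satellite cell and tendon genes failed without 9M_UT replicate 1 (medians 0.08, 0.28 and 0.31), satellite and Schwann cell genes without 9M_UT replicate 2 (medians 0.23 and -0.02) and interferon genes without 9M_UT replicate 3 (median -0.26). The Schwann cell result also ended without 9M_PoW+DT replicate 3 (median -0.14, adjusted p = 0.0505). Other medians moved while they passed. Without 6M_UT replicate 1 embryonic genes stood at 0.60, endothelial at 0.17 and progenitor genes at 0.11, and without 6M_UT replicate 3 endothelial genes at 0.15, leukocyte genes at 0.21 and immediate early genes at 0.43. Without 9M_UT replicate 1 embryonic genes stood at 0.53, ribosomal proteins at -0.05, matrix genes at 0.14, Schwann cell genes at -0.36 and interferon genes at -0.21, and without 9M_UT replicate 3 embryonic genes at 0.15 and Schwann cell genes at -0.235.

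**Figure D3:**
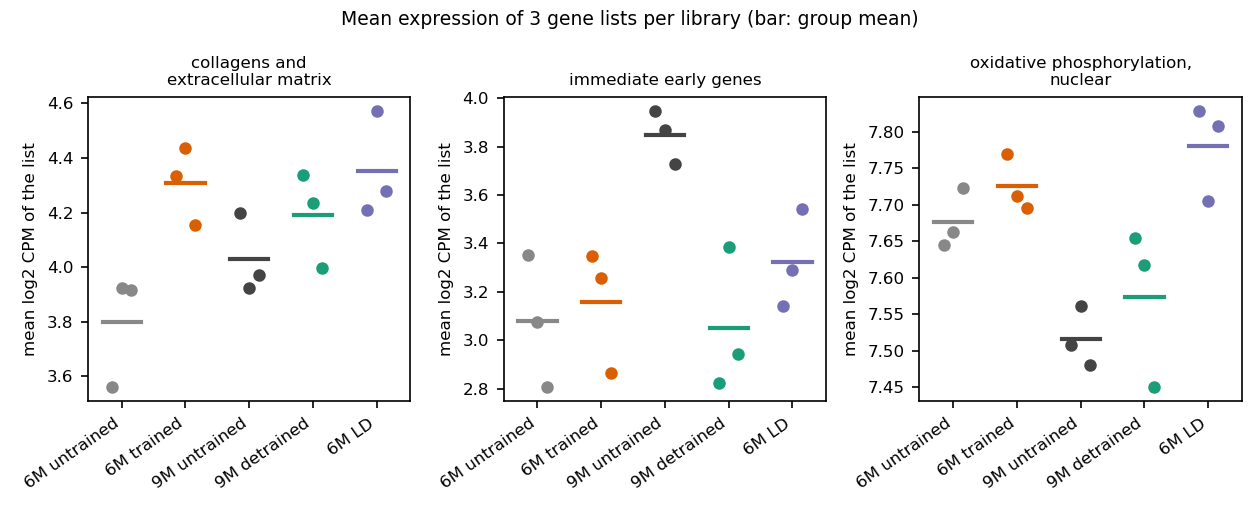
Mean log2 CPM of the genes of 3 lists in each of the 15 libraries, with 1 point per library and a bar for the group mean. Matrix genes lie at 3.56 to 3.93 in 6M_UT, 4.15 to 4.44 in 6M_PoW and 4.21 to 4.57 in 6M_POW_LD, and immediate early genes lie at 3.73 to 3.95 in 9M_UT and at 2.83 to 3.39 in 9M_PoW+DT.

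The LD libraries, titled as trained mice of 6 months, were compared with untrained mice of that age. Matrix genes rose by a median of 0.52 on the log2 scale over 33 genes, progenitor markers by 0.38 over 14, leukocyte markers by 0.65 over 16 and interferon-stimulated genes by 0.43 over 18. Tendon, Schwann cell, satellite cell, endothelial and pericyte markers rose by 0.60, 0.75, 0.38, 0.31 and 0.26, and nuclear oxidative phosphorylation genes by 0.13. The Schwann cell rise came from 6M_POW_LD replicate 5, without which the median was 0.04 (adjusted p = 0.557). Atrophy genes fell by 0.72, ribosome biogenesis genes by 0.16 and ribosomal proteins by 0.11. No list of this comparison passed otherwise in camera, with adjusted p = 0.143 to 0.627 with an estimated correlation. The imprinted non-coding RNA H19 was higher at 603 ± 73.9 against 195 ± 56.5 CPM, while Cst6 was lower at 1.12 ± 0.457 against 7.26 ± 1.59 CPM.

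Against untrained mice 757 of 15181 genes were called, 327 higher and 430 lower. On the log2 scale, the fold change was 1.63 ± 0.24 for H19 (chromosome 7, 142575529 to 142578143, edgeR adjusted p = 0.00359), -2.68 ± 0.27 for Cst6 (adjusted p = 1.8e-05), -2.10 ± 0.26 for Epb41l4b (adjusted p = 1.5e-04) and -1.83 ± 0.28 for Lgals4 (adjusted p = 9.2e-04). Over all genes, 9 matrix genes, 7 progenitor markers, 2 leukocyte markers, 1 satellite cell marker and 1 interferon-stimulated gene were called higher, beside 19, 8, 7, 2 and 4 adjusted over the list alone. On the log2 scale, the fold change was 0.52 ± 0.09 for Col4a1, 0.97 ± 0.17 for Col5a2, 0.67 ± 0.12 for Pdgfra, 0.76 ± 0.14 for Lyz2, 0.57 ± 0.11 for the integrin gene Itga7 and 1.34 ± 0.28 for Gbp3. Rpl4 and Noc2l of ribosome assembly fell by 0.34 ± 0.06 and 0.34 ± 0.09. The ubiquitin ligase gene Fbxo32 stood at 356 ± 36.4 CPM in LD and 1082 ± 655 CPM in untrained libraries and did not pass (edgeR adjusted p = 0.119). The list results had adjusted p of 1.0e-12 for the matrix, 7.9e-08 for progenitor and 1.8e-07 for leukocyte markers, and 1.3e-05 for atrophy genes. It was 9.3e-04 for interferon-stimulated genes, 0.00243 for ribosome biogenesis, 0.00358 for tendon markers and for nuclear oxidative phosphorylation, 0.00498 for endothelial markers, 0.00744 for ribosomal proteins, 0.0219 for Schwann cell, 0.0232 for satellite cell and 0.0425 for pericyte markers. None passed with the other form of camera, with adjusted p = 0.143 with an estimated correlation for matrix, progenitor and leukocyte genes and adjusted p = 0.226 to 0.627 for the others. By fry, 6 of these lists passed, at an adjusted p of 0.0101 for the matrix, 0.00825 for progenitor and for leukocyte markers, 0.0161 for satellite cell markers, 0.0341 for interferon-stimulated genes and 0.0450 for ribosome biogenesis. Growth regulators (median 0.02) and proteostasis genes (median -0.05) passed only by fry, at an adjusted p of 0.0264 and 0.0450, beside 0.172 and 0.106 by camera. DESeq2 called 1190 genes and limma-voom 809. The count was 288, 403 and 437 without 6M_POW_LD replicates 5, 4 and 6 and 386 without 6M_UT replicate 1, and 387 in a fit of only these 2 groups. The call of Gbp3 ended without 6M_POW_LD replicate 5 (adjusted p = 0.0613). That of Noc2l ended without any 6M_UT or 6M_POW_LD replicate (adjusted p = 0.0635 to 0.124), with thinned counts (adjusted p = 0.0560), in the fit of only these 2 groups (adjusted p = 0.0741) and with 1 surrogate variable (adjusted p = 0.0887). Atrophy genes stood at -0.28 without 6M_UT replicate 1, pericyte markers at 0.40 without 6M_UT replicate 3 and ribosomal proteins at -0.18 without 6M_POW_LD replicate 6. The pericyte result ended without 6M_UT replicates 1 or 2 or 6M_POW_LD replicates 5 or 6 (adjusted p = 0.0554 to 0.155), the satellite cell result without 6M_UT replicate 2 or 6M_POW_LD replicate 6 (adjusted p = 0.108 and 0.0802), the endothelial result without 6M_POW_LD replicate 6 (median 0.20, adjusted p = 0.0830), and the ribosomal protein and Schwann cell results without 6M_POW_LD replicate 5 (medians -0.08 and 0.04, adjusted p = 0.0633 and 0.557).

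The LD libraries were also compared with the other trained libraries of the same age, since the titles put both in one condition. Tceal7 was higher in LD libraries at 23.2 ± 3.24 against 8.76 ± 1.197 CPM, the ciliary neurotrophic factor receptor gene Cntfr at 17.4 ± 1.58 against 5.88 ± 1.71 CPM and the imprinted gene Peg10 at 6.79 ± 0.869 against 1.97 ± 0.916 CPM. Cst6 was lower at 1.12 ± 0.457 against 5.85 ± 0.629 CPM and Tekt1 at 1.57 ± 0.209 against 5.50 ± 1.56 CPM. The calcium-handling genes Casq1 and Pvalb rose by 0.54 ± 0.08 and 0.44 ± 0.08 on the log2 scale, and the fast fibre list by a median of 0.15 (adjusted p = 0.986 with an estimated correlation). Matrix genes had a median of 0.06 and did not pass (adjusted p = 0.712).

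Here 365 of 15181 genes were called, 195 higher and 170 lower. The edgeR adjusted p was 3.7e-05 for Tceal7, 6.3e-04 for Cntfr, 0.00689 for Peg10, 1.5e-04 for Cst6, 0.00107 for Tekt1, 8.2e-04 for Casq1 and 0.00477 for Pvalb. Atrophy genes fell by a median of 0.34 (adjusted p = 0.0134), and Schwann cell markers and erythroid markers rose by 0.60 and 1.15 (adjusted p = 0.0419 for both and for fast fibre genes), all with adjusted p = 0.986 with an estimated correlation. Bpgm of red blood cells rose by 0.43 ± 0.07, while the haemoglobin gene Hbb-bs stood at 545 ± 556 CPM in LD and 241 ± 27.3 CPM in trained libraries. Mbp of myelin stood at 26.5 ± 14.7 and 12.8 ± 2.97 CPM, and Fbxo32 at 356 ± 36.4 and 973 ± 359 CPM. DESeq2 called 675 genes and limma-voom 380. The count was 157, 217 and 213 without 6M_POW_LD replicates 4, 5 and 6 and 185, 231 and 161 without 6M_PoW replicates 1, 2 and 3. The erythroid list had a median of -0.10 and an adjusted p of 0.681 without 6M_POW_LD replicate 6, and the Schwann cell list a median of -0.07 and an adjusted p of 0.880 without 6M_POW_LD replicate 5. The fast fibre result ended without 6M_UT replicate 1, 6M_PoW replicates 1 or 2 or 6M_POW_LD replicates 4 or 6 (medians 0.10 to 0.15, adjusted p = 0.0571 to 0.297) and stood at 0.24 without 6M_PoW replicate 3. The atrophy result ended without 6M_PoW replicate 3 or 6M_POW_LD replicate 5, with medians of -0.15 and -0.31 (adjusted p = 0.129 and 0.0784). Without 6M_UT replicate 1 or 6M_PoW replicates 1 or 3, the Schwann cell result (adjusted p = 0.0558 to 0.184) and the erythroid result (adjusted p = 0.0571 to 0.101) ended too, and the Schwann cell median was 0.39 without 6M_PoW replicate 3.

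The myosin heavy chain genes that mark fibre types did not pass in the training or the detraining comparison. Myh1 stood at 13878 ± 1644 CPM in trained and 11360 ± 987 CPM in untrained mice of 6 months (log2 fold change 0.29 ± 0.10, edgeR adjusted p = 0.359), and at 0.17 ± 0.10 after detraining. The log2 fold change of Myh2 was 0.15 ± 0.22 after training and -0.08 ± 0.22 after detraining, and that of Myh4 was -0.45 ± 0.22 and -0.01 ± 0.22. The slow myosin Myh7 ran from 0.495 to 223 CPM over the 15 libraries, both in 9M_UT, and had log2 fold changes of -0.71 ± 1.67 and -0.51 ± 1.64. The regulator of mitochondrial biogenesis Ppargc1a stood at -0.06 ± 0.39 and 0.20 ± 0.39, myostatin (Mstn) at -0.37 ± 0.27 and -0.22 ± 0.27, Vegfa at -0.29 ± 0.24 and 0.05 ± 0.24 and Igf1 after detraining at -0.25 ± 0.22. Lists that passed camera in none of the 7 comparisons were slow fibre genes, neuromuscular junction genes, growth regulators, exercise response regulators, citric acid cycle genes, proteostasis genes, clock genes, cell cycle genes, DNA methylation enzymes, candidate muscle memory genes and Hox genes. Their medians after training and after detraining were -0.15 and -0.29 for slow fibre genes, 0.20 and 0.21 for the neuromuscular junction, -0.05 and -0.06 for growth regulators, and -0.09 and -0.04 for exercise response regulators. They were 0.08 and 0.02 for the citric acid cycle, 0.00 and -0.07 for proteostasis, -0.18 and 0.15 for the clock, 0.00 and -0.24 for the cell cycle, 0.00 and -0.03 for DNA methylation enzymes, 0.04 and 0.03 for candidate memory genes and 0.01 and 0.02 for Hox genes. The clock list holds genes of opposite phase, whose shifts can cancel in its median and in the set test. Clock genes of opposite phase moved apart by 1.79 on the log2 scale between the 9-month groups. Median and mean differed in sign after training for growth regulators (mean 0.06), Hox genes (mean -0.04), cell cycle genes (mean 0.05) and DNA methylation enzymes (mean 0.06).

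**Figure D4:**
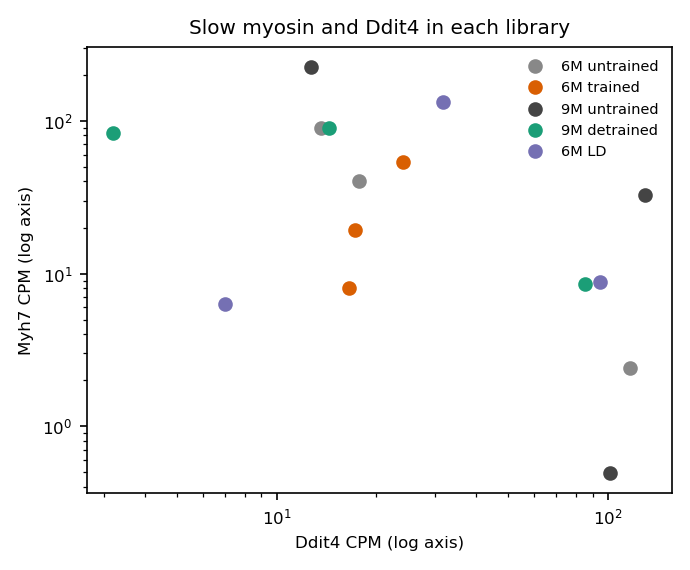
Levels in CPM of Myh7, the slow myosin heavy chain, against those of Ddit4, both on log axes, with 1 point per library in the colour of its group. Myh7 runs from 0.495 to 223 CPM and Ddit4 from 3.21 to 130 CPM, and libraries of one group lie far apart.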

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

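The tests of untrained mice as the source of the LD libraries, of one library alone, of a lasting effect of earlier training and of library size were chosen after the result was seen.

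A closer look was given to 14 results because the training effect at 6 months and the detraining effect at 9 months differed in a test of the difference itself. The log2 difference was -1.82 for Fosl2, -3.54 for Nr4a2, -6.52 for Tmem232 and -2.03 for Trp53i11 (edgeR adjusted p = 0.0330 each). The medians of lists were 0.20 for fast fibre genes, -0.25 for oxidative phosphorylation genes of the mitochondrial genome, 0.15 for glycolysis, 0.17 for ribosomal proteins, -0.33 for the matrix, -0.41 for endothelial, -0.40 for progenitor and -0.42 for leukocyte markers, 1.197 for adipocyte markers (0.53 without 9M_PoW+DT replicate 3, adjusted p = 0.0586) and -0.36 for immediate early genes. None of these lists passed with an estimated correlation (adjusted p = 0.0993 to 0.558). For the 4 gene calls, 4 of 100 splits drawn from 200, the real one included, had as many, with 14 as the highest other. This share lies just under 0.05. It comes from a sample of splits and is 1 of several such tests, so chance is not firmly excluded. In edgeR, which had 1414 genes at an unadjusted p under 0.05, the count was 0 without 6M_UT replicate 2, 6M_PoW replicates 1 or 2, 9M_UT replicates 2 or 3 or 9M_PoW+DT replicate 3, and limma-voom called 0 and DESeq2 111. Chance cannot be excluded for the 10 lists either, as 24 of 100 splits had as many, with 15 as the highest other. The calls, and for Tmem232, Fosl2 and Nr4a2 their direction, rest on the titles of the 9-month libraries. With those groups exchanged none of the 4 genes passed in edgeR, with Tmem232 at 4.53 (adjusted p = 0.362), Fosl2 at 0.97 and Nr4a2 at 1.86 (adjusted p = 0.612 for both) and Trp53i11 at -0.50 (adjusted p = 0.747).

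The LD libraries differed from the other trained libraries in 365 genes, with 1 as the highest of the other splits, and 10 splits are too few for a share under 0.05. Called genes did not lie together on chromosomes, with 7 neighbour pairs against a mean of 8.47 for permuted genes (0.827 times, permutation p = 0.75). This argues against runs of adjacent changed genes. It cannot exclude another genetic background that changed few genes in each linked segment, since only adjacent called genes were counted. The trend with GC content and transcript length between these groups was small, with an SD of 0.0209 on the log2 scale, and 94.2% of the calls remained once it was removed (median shift 0.0141), which argues against such a trend as the whole cause. Untrained mice, as the treatment field says, stay open: the matrix list was higher by 0.52 than in untrained mice, and by the bounds first set this excluded untrained mice, but tendon markers passed in the same direction (0.60, adjusted p = 0.418 with an estimated correlation), which another dissection could give. Schwann cell markers did so only with 6M_POW_LD replicate 5 (0.04 without it, adjusted p = 0.557), and the condition on both lists was added after the result was seen.

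Immediate early genes were higher in untrained than in detrained mice of 9 months in every library, and the median without one untrained library stayed at -0.40 or further from 0, which argues against one library alone. Another time of day at collection may contribute, since clock genes of opposite phase moved apart by 1.79 on the log2 scale between these groups. The trained mice of 6 months had a mean clock difference of -1.47, between those of 9M_UT (-1.06) and 9M_PoW+DT (-2.85). Their replicate 2 lay near the detrained libraries in Dbp (30.1 against 33.9 to 42.1 CPM), and they did not have raised immediate early genes. Untrained mice of 6 months stood at -2.79, with a wide spread in the clock gene Arntl (26.7 ± 16.7 CPM). Clock means thus also differed in the training comparison and between the untrained groups, and time of day is not excluded there either. A lasting effect of earlier training stays open, with a median of -0.12 between detrained and 6-month untrained mice. By the bounds first set this value excluded it, and the further condition, that 2 SE of the difference of the list means be allowed for, was added after the result was seen.

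Slow fibre genes spread widely between libraries of one group. The amount of slow muscle in each sample could be a source, and the deviations of these genes had a median correlation of 0.53, between the bounds set for and against it. With libraries permuted within groups for each gene, the highest median was 0.23 (permutation p = 0.0001). The genes thus varied together, but this does not show the source. Library size was argued against by a Spearman correlation of -0.025. No biological explanation was tested, because the labels give none for single mice.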

How the results depend on the processing

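The fit with 1 surrogate variable, the gene sets at an unadjusted p under 0.01 and the lists without one library were chosen after the data had been seen. Of 68 list results, 68 stayed past the threshold with relative log expression factors and with no filter, 67 with thinned counts, 61 with a stricter filter, 50 of 51 with the replicate block, 792 of 867 without one library, 8 by fry and 2 with an estimated correlation. In LD against trained mice 2 medians changed sign without one library, with ranges of -0.072 to 0.86 for Schwann cell and -0.10 to 1.56 for erythroid markers. The count of calls in trained against untrained mice was 8 with no filter, 112 by DESeq2, 4 with only the 2 groups in the fit, 29 with LD libraries added to trained, 15 with 1 surrogate variable and 0 to 10 without one library. In detrained against untrained mice it was 0 with a stricter filter, 30 by DESeq2, 0 by limma-voom, 18 with only the 2 groups and 1 to 6 without one library. For the difference it was 10 with no filter, 111 by DESeq2, 0 by limma-voom, 0 with the 9-month groups exchanged, 2 and 1 with LD libraries added to trained and to untrained, 11 with 1 surrogate variable and 0 to 26 without one library. In detrained against trained mice it was 81 with no filter, 348 by DESeq2, 24 by limma-voom, 124 with LD libraries added to trained, 99 with 1 surrogate variable and 0 to 109 without one library. In older against younger untrained mice it was 10 with no filter, 0 with a stricter filter, 4 with thinned counts, 58 by DESeq2, 0 by limma-voom, 10 with only the 2 groups, 0 with the 9-month groups exchanged, 9 with 1 surrogate variable and 1 to 15 without one library. In LD against untrained mice it was 1190 by DESeq2, 387 with only these 2 groups and 288 to 827 without one library, and in LD against trained mice 675 by DESeq2 and 157 to 428 without one library. DESeq2 called 1 gene in the same direction in both the training and the detraining comparison. Genes it gave no adjusted p (1452 in the training comparison) stay out of its counts. The cause was not tested.

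With the replicate number as a block the counts were 1 in trained against untrained, 19 in detrained against trained and 5 in older against younger mice, Fosl2 lost its calls after detraining (-1.39, adjusted p = 0.116) and in the difference (-1.82, adjusted p = 0.0928), and Myh7 after detraining stood at 0.023. The numbers did not pair the libraries: correlations of same-numbered libraries ran from -0.43 to 0.35, 7 of 18 pairs were over 0.1 and 4 of 12 libraries had their highest correlation outside their group with their own number. The cause was not tested.

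The genes higher after training, chosen again under each alternative (96 to 377 genes, against 199), had a detraining median of -0.023 with no filter, 0.041 with the 9-month groups exchanged, 0.0069 with LD libraries added to trained and -0.081 to 0.012 without one library, and the lower genes (119 to 339, against 221) -0.028 with the exchange and -0.0088 to 0.053 without one library. The exchange reversed the detraining comparison by construction: Tmem232 5.53, Fosl2 1.40, Nr4a2 2.701, Atf3 1.78, Klf4 1.37, Ankrd1 0.88, Flt1 0.35, Bnip3 0.31, mt-Co1 0.27, mt-Co2 0.32, Lep -2.46, Adipoq -1.11, Sparc -0.37, Igf1 0.25, Myh1 -0.17, Myh2 0.082, Myh4 0.0096, Myh7 0.51, Ppargc1a -0.20, Mstn 0.22 and Vegfa -0.054. It also reversed Tmem232 (4.53), Fosl2 (0.97), Nr4a2 (1.86), Tpi1 (-0.028) and mt-Co1 (0.091) in the difference, and Tmem232 (-0.61), Nr4a2 (-0.36) and Fosl2 (-0.33) in older against younger mice. LD libraries added to untrained reversed Myh2 after training (-0.021) and Lyz2 in older mice (-0.053), and added to trained Ppargc1a (0.12). In the detraining comparison 1 surrogate variable reversed Myh4 (0.16), Mstn (0.034) and Vegfa (-0.16), and limma-voom Myh7 (1.17). Without one library the values ran from -1.68 to 0.32 for Myh7 and -0.24 to 0.14 for Ppargc1a after training, and after detraining from -0.20 to 0.11 for Myh2, -0.24 to 0.13 for Myh4, -1.09 to 1.84 for Myh7, -0.30 to 0.54 for Ppargc1a and -0.12 to 0.28 for Vegfa, and Hbb-bs in LD against trained mice from -0.10 to 1.59. The cause was not tested.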

Other observations

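The splits of the libraries were chosen before the result was seen, and no test in this part was chosen after it. The component described last is not a test and was not among the planned analyses.

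Other splits of the same 6 libraries were fitted for each comparison, and 10 splits are too few for a share under 0.05. Trained against untrained mice gave 0 calls in edgeR (1455 genes at an unadjusted p under 0.05, 112 calls by DESeq2 and 0 by limma-voom), with 0 as the highest other count and 10 of the 10 splits as large, and 9 lists, with 15 as the highest other. Detrained against untrained mice gave 3 calls (highest other 8) and 9 lists (highest other 12). Detrained against trained mice gave 44 calls (highest other 0) and 10 lists (highest other 15). Older against younger untrained mice gave 2 calls (highest other 0) and 13 lists (highest other 12). LD against untrained libraries gave 757 calls (highest other 1) and 13 lists (highest other 13), and LD against trained libraries gave 365 calls (highest other 1) and 4 lists (highest other 11). In 5 of these 6 comparisons, at least 1 other split gave as many lists as the real one.

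After the group means were removed, the first component held 35.6% of the variance left. On one side it had Ddit4 (3.22 to 130 CPM), Fkbp5 (30.8 to 357 CPM), Pdk4 (430.9 to 6140.2 CPM) and Trim63 (152 to 1279.5 CPM), and on the other Myh7, Tnnc1 (0.0551 to 22.1 CPM), Tnnt1 (0.551 to 33.3 CPM) and Dbp (6.01 to 115 CPM).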
